A study of Mus musculus with 10 samples.

How the data were processed

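Gene expression was measured on Affymetrix-type mouse expression arrays in whole hippocampi from 10 adult female SJL/J mice at 2 days after an axonal lesion. Per the labels, 5 mice had the lesion alone (AxL) and 5 received T cells specific for proteolipid protein before the lesion (TPlp+AxL). Each array is 1 mouse and each group has replicate numbers 1 to 5. The deposited table holds log2 expression values of 45101 probe sets that the authors made with RMA, per the submitters' processing notes. The software and version behind RMA are not given in the sources used here. The deposited values ran from 5.45 to 14.86 with 0 missing values and 0 identical arrays. The arrays shared a median near the same level but not an identical distribution.

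The 64 Affymetrix control probe sets were left out, and the other 45037 were tested with no filter and no further normalization. Gene symbols came from the platform's annotation and were updated through Entrez identifiers with a mouse gene table of assembly GRCm38.p6, which matched 34741 of the 34945 probe sets with 1 symbol. A further 932 probe sets listed several genes and 9160 listed none. The 34945 probe sets represented 18193 genes, and each gene was represented by its probe set with the highest mean over the 10 arrays.

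TPlp+AxL was compared with AxL by limma 3.58.1 (lmFit and eBayes without a trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all 45037 probe sets and a threshold of 0.05 on the adjusted p. A probe set or gene is described as having risen or fallen only where it passed that threshold. Each reported log2 change is the mean of TPlp+AxL minus the mean of AxL, with its standard error (SE) or 95% interval from the same fit. The p-values of single probe sets measure the spread between these mice. The 3 Dpysl3 probe sets were also compared by an exact two-sided permutation test over all 252 relabellings of the 10 arrays, with Benjamini-Hochberg adjustment over the 3, and the smallest p that this test can give is 0.00794. The number of arrays limits the precision of every value. On simulated data of the same size, with 5 runs of 200 changed probe sets each, the test recovered 59.1% of log2 changes of 0.3, 86.7% of changes of 0.5 and 99.1% of changes of 1, with 5.09% false calls. The simulated noise was independent between probe sets, without correlated genes, differences between arrays or a shift with signal level. The real arrays had these, so the rates may not hold for them.

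The analysis used 32 gene lists: immature neurons and neurogenesis, neural stem and progenitor cells, cell cycle, T cells, cytotoxic and NK cells, B cells and plasma cells, cytokines, interferon gamma response, type I interferon response, MHC class II presentation, MHC class I presentation, chemokines, endothelium and leukocyte adhesion, homeostatic microglia, reactive microglia and macrophages, complement, neutrophils and monocytes, reactive astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, mature neurons and synapses, axonal growth and neurotrophic factors, immediate early genes, glucocorticoid response, circadian clock, heat shock, choroid plexus, meninges and fibroblasts, blood, thalamus and habenula, hippocampal subfields, and neocortex and subiculum. Several genes stand in more than 1 list. Lists were tested by limma's camera with a preset correlation between genes of 0.01 and at least 5 measured genes, two-sided, adjusted over the 32 lists. Each was tested again with the correlation estimated from the data and with fry. The preset value treats genes as nearly independent, while the estimates ran from -0.013 (immature neurons and neurogenesis) to 0.795 (choroid plexus). Camera p-values with the preset value therefore depend on the number of genes and do not measure the spread between mice. Members were counted as higher or lower after adjustment over all probe sets and after adjustment over the list alone.

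The named genes followed a rule: Dpysl3 and the panel Dcx, Cd3e, Ifng, Il1b, Tnf, H2-Aa, Gfap, Aif1 and Itgam; the 12 higher and the 12 lower genes with the largest log2 change of their representative probe set among those past the threshold; and from each list the up to 4 members past the threshold with the largest change, or the 2 with the smallest p where none passed. Where another probe set of a named gene differed in sign or in its side of the threshold, its value is given. The groups, the test, the lists and this rule were set before the data were examined.

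The alternatives were a trended and robust variance, leaving out the dim part of the probe sets, subtracting each array's median, repeating quantile normalization, array weights, 1 probe set per gene, leaving out probe sets with the endings for shared sequence, a block for the replicate number, the choroid plexus list mean as a covariate, each array left out in turn, averaging the probe sets of a gene for the lists, and an adjusted p under 0.10. Cyclic loess normalization, a block for a division of the arrays that crosses the groups, and the removal of 3 arrays with choroid plexus signal or of 2 arrays that stood apart were added after the data were seen. Other divisions of the 10 arrays into 5 and 5 were tested on 100 of the 126 possible ones, the real one included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.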

Results

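Whole hippocampi of 10 adult female SJL/J mice were profiled at 2 days after an axonal lesion, 5 with the lesion alone (AxL) and 5 that had also received T cells directed at proteolipid protein, a major protein of myelin (TPlp+AxL). Each mouse contributed 1 array with 45037 probe sets apart from controls. The median log2 signal of the arrays ran from 7.88 to 7.92. Its mean was 7.88 in AxL and 7.91 in TPlp+AxL (exact permutation p = 0.00794, adjusted p = 0.0437 over the array measures), and the 99th percentile was 12.96 and 12.83 (exact permutation p = 0.0397, adjusted p = 0.0728). The highest correlation of an array with any other averaged 0.995 in AxL and 0.997 in TPlp+AxL (exact permutation p = 0.00794, adjusted p = 0.0437).

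The comparison of TPlp+AxL with AxL asked which hippocampal transcripts differ after a lesion when myelin-specific T cells are present. Interferon-inducible genes, chemokines and genes that leukocytes express rose. Iigp1, an interferon-inducible GTPase that acts against intracellular pathogens, had a log2 value of 8.75 ± 0.23 (SD, n = 5) in AxL and 11.20 ± 0.96 (SD, n = 5) in TPlp+AxL, a 5.45-fold difference (log2 change 2.45, SE 0.37, adjusted p = 0.0101). Gbp2, a guanylate-binding GTPase induced by interferons, rose 5.25-fold (log2 change 2.39, SE 0.23, adjusted p = 0.00115), and Chil3, a chitinase-like protein of monocytes and macrophages, rose 4.54-fold (log2 change 2.18, SE 0.15, adjusted p = 0.000282). The strongest declines were smaller, led by the chemokine Ccl3, which fell by 0.71 on the log2 scale (SE 0.14, adjusted p = 0.0462). For each of these 4 genes the 5 TPlp+AxL arrays lay entirely above, or for Ccl3 below, the 5 AxL arrays.

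Of the 45037 probe sets, 376 passed the threshold, with 291 higher and 85 lower in TPlp+AxL, and they covered 270 named genes (201 higher and 69 lower). The higher set held 70 probe sets with a change of at least 2-fold and the lower set held 0, while 6453 probe sets of either direction had an unadjusted p under 0.05 in limma. Over all 45037 probe sets the groups did not overlap in 1615 (3.59%), where chance gives 0.794%, and these include 281 of the 291 higher and 84 of the 85 lower probe sets, which the test favours for being apart. The split was 269 higher and 210 lower after each array's median was subtracted, and 348 higher and 43 lower after cyclic loess normalization. The total ran from 185 without TPlp+AxL 4 to 460 without AxL 2, was 220 without AxL 5, 240 without TPlp+AxL 3 and 243 without TPlp+AxL 5, and fell to 1, Chil3, with AxL 3, AxL 5 and TPlp+AxL 1 left out together, where 4743 probe sets had an unadjusted p under 0.05 in limma.

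By the brightest probe set of each gene, the 12 largest increases were those of Iigp1, Gbp2, Chil3, Gbp6, Igtp, Plac8, Cxcl9, AW112010, Clec7a, Gbp7, Cxcl11 and Il6. Gbp6 (log2 change 2.09), Gbp7 (1.78) and Igtp (2.06) encode interferon-induced GTPases of the same kind as Gbp2 and Iigp1, and AW112010 (1.84) is an interferon-inducible transcript. Plac8 (1.92) marks monocytes and other leukocytes. Clec7a (1.83), also called dectin-1, is a receptor of myeloid cells for fungal glucans. The cytokine Il6 rose by 1.70 (SE 0.19, adjusted p = 0.00221). Adjusted p ran from 0.000282 for Chil3 to 0.0192 for Gbp6, and in all 12 genes each of the 5 TPlp+AxL arrays lay above each of the 5 AxL arrays. The second probe sets of Cxcl9 (0.15) and Cxcl11 (0.24) did not pass.

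**Figure D1:**
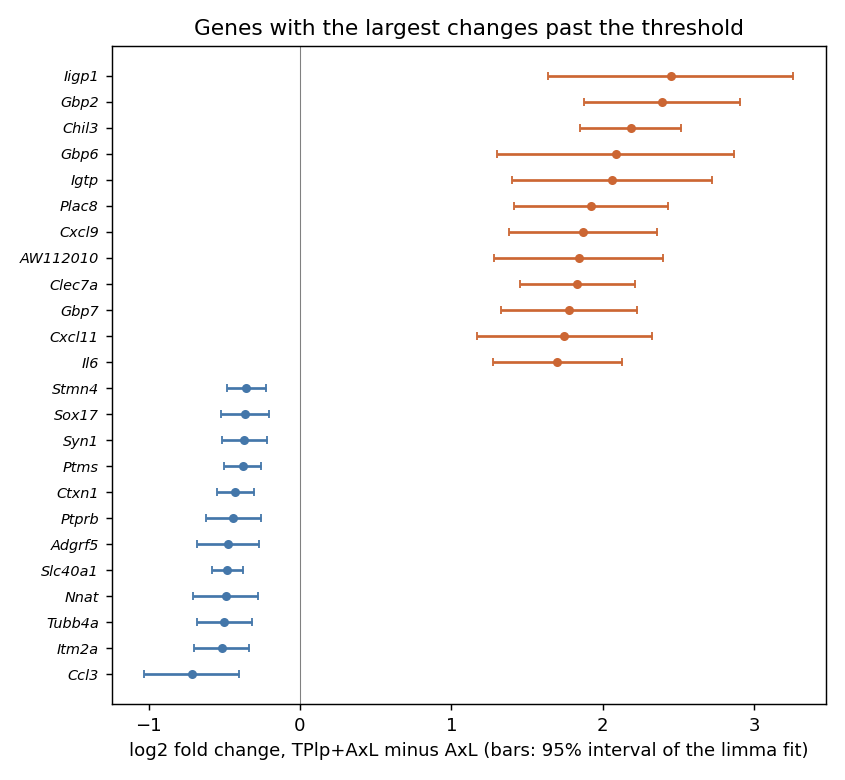
Log2 fold change (TPlp+AxL minus AxL, horizontal axis) of the 12 higher and 12 lower genes with the largest change past the threshold by their brightest probe set; points are the difference of the means of 5 arrays each and bars the 95% interval of the limma fit. The higher genes reach 2.45 for Iigp1, and the lower genes reach -0.71 for Ccl3.

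Genes induced by interferon gamma, the main macrophage-activating cytokine of T helper 1 cells, moved most as a group. All 26 measured members were positive, 18 rose and 22 were higher when adjusted over the list alone, with a median log2 change of 1.18 (camera adjusted p = 1.79e-35, adjusted p = 0.0442 with an estimated correlation). Ifng itself had a log2 change of 0.41 and did not pass (adjusted p = 0.0706, 95% interval 0.21 to 0.61). It passed without TPlp+AxL 2 (adjusted p = 0.00063), the array with the lowest interferon gamma response in its group. In the type I interferon response, which overlaps in its targets, 6 of 32 members rose and 26 did when adjusted over the list alone, with a median of 0.41 (camera adjusted p = 2.0e-26, adjusted p = 0.0868 with an estimated correlation). Its largest increases were Ifi204 (1.55) and Zbp1 (0.94), which sense foreign nucleic acids, the ubiquitin ligase Dtx3l (0.63) and the ADP-ribosyltransferase Parp14 (0.59). Second probe sets of Dtx3l (0.35) and Parp14 (0.19) did not pass.

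Some antigen presentation genes also rose, all of them in the MHC class I list. In the MHC class I list 4 of 14 members rose, 12 when adjusted over the list alone, with a median of 0.54 (camera adjusted p = 1.06e-16, adjusted p = 0.0896 with an estimated correlation). The 4 were Psmb9 (1.58), a subunit of the immunoproteasome, Nlrc5 (1.29), a transactivator of class I genes, the peptide transporter subunit Tap1 (0.73) and the tapasin-like Tapbpl (0.23). The other probe sets of Tap1 (-0.04, 0.07 and 0.04) and Tapbpl (0.10) did not pass. In the MHC class II list 0 of 12 members passed over all genes in limma and 6 did when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 2.3e-08, adjusted p = 0.0704 with an estimated correlation). H2-Aa, a class II chain, had a log2 change of 1.05 (adjusted p = 0.0779) and Cd74, the invariant chain, 0.99 (adjusted p = 0.0556), each with the 5 TPlp+AxL arrays above the 5 AxL arrays. Both passed without TPlp+AxL 2, where H2-Aa had an adjusted p of 0.0114 and Cd74 of 0.0108, and Cd74 passed without TPlp+AxL 3 (adjusted p = 0.0419). Without TPlp+AxL 4 the limma adjusted p was 0.206 for H2-Aa and 0.145 for Cd74.

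Chemokines rose as a group with a median of 0.32, 12 of 23 members higher and 1 lower, or 15 and 3 when adjusted over the list alone (camera adjusted p = 4.8e-17, adjusted p = 0.0442 with an estimated correlation). Cxcl9 (1.87), Cxcl10 (1.56) and Cxcl11 (1.75) bind the receptor Cxcr3 of activated T cells, and Ccl2 (1.64, adjusted p = 0.000779) attracts monocytes. Ccl3 was the member that fell. Among cytokines 7 of 25 rose, 14 when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 9.5e-15, adjusted p = 0.0251 with an estimated correlation). They included Il6, Il1b (1.11, adjusted p = 0.00171), Ltb (0.41), the gene of lymphotoxin beta, and Il1a (0.35), and all 5 TPlp+AxL arrays were above the AxL arrays for each. Tnf had a log2 change of 0.15 and did not pass (adjusted p = 0.187).

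Transcripts of T cells and cytotoxic cells were higher. In the T cell list 7 of 36 members rose, and 17 were higher and 1 lower when adjusted over the list alone, with a median of 0.10 (camera adjusted p = 1.06e-16, adjusted p = 0.0653 with an estimated correlation). The lymphocyte membrane protein Ms4a4b (1.67), the lymphocyte GTPase Gimap4 (0.90) and Cd3g (0.87) and Cd3d (0.63), CD3 chains of the T cell receptor complex, rose. Another CD3 chain, Cd3e, had a log2 change of 0.12 and did not pass in limma (adjusted p = 0.255). A second Ms4a4b probe set had 0.01. In the cytotoxic and NK cell list 4 of 14 rose, 5 when adjusted over the list alone, with a median of 0.09 (camera adjusted p = 3.5e-08, adjusted p = 0.0653 with an estimated correlation). They were the chemokine Ccl5 (0.88), granzyme B (Gzmb, 0.52), the receptor chain Klrd1 (0.52) and Nkg7 (0.38), a granule protein. The list of B cells and plasma cells had a median of 0.04 with 0 of 12 members past the threshold in limma, over all genes or when adjusted over the list alone. Its camera call (adjusted p = 0.0310, adjusted p = 0.326 with an estimated correlation) was lost without AxL 4 (0.185), TPlp+AxL 2 (0.0633) or TPlp+AxL 4 (0.0546), and after cyclic loess normalization (0.389).

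Several genes of neutrophils, monocytes and reactive myeloid cells rose. In neutrophils and monocytes 8 of 17 rose, 11 when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 3.4e-17, adjusted p = 0.0251 with an estimated correlation). Beside Chil3 and Plac8, S100a9 (1.18) and S100a8 (1.14), the abundant calcium-binding proteins of neutrophils, rose. In reactive microglia and macrophages 9 of 33 rose and 1 fell, 17 and 3 when adjusted over the list alone, with a median of 0.26 (camera adjusted p = 1.9e-11, adjusted p = 0.0896 with an estimated correlation). Clec7a, Cybb (0.93), a subunit of the phagocyte oxidase, lysozyme (Lyz2, 0.90) and Ptprc (0.78), which encodes the leukocyte antigen CD45, led this list. A further Cybb probe set (0.12) and a second Ptprc probe set (0.12) did not pass. Aif1 (0.40, adjusted p = 0.181) and Itgam (0.10, adjusted p = 0.706, and 0.05 to 0.20 with 1 array left out), general markers of microglia and macrophages, did not pass. Neither did the homeostatic microglia list, which holds genes of resident cells, with 13 of 18 members negative and a median of -0.11 (camera adjusted p = 0.114). The complement list had a median of 0.08 with 0 of 11 members past the threshold in limma and 2 when adjusted over the list alone, Cfb (0.39, adjusted p = 0.0681) and Itgb2 (0.50, adjusted p = 0.0723) (camera adjusted p = 0.000628, adjusted p = 0.254 with an estimated correlation). Cfb encodes complement factor B and Itgb2 an integrin chain of complement receptors, and both passed without TPlp+AxL 2 (adjusted p = 0.0325 and 0.00601). Without TPlp+AxL 4 the limma adjusted p was 0.182 for Cfb and 0.189 for Itgb2. The median of the complement list was 0.04 without TPlp+AxL 3, 0.13 without AxL 3 and 0.14 without TPlp+AxL 2, and the list passed in each case.

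Of 24 measured genes of reactive astrocytes, 2 rose and 9 did when adjusted over the list alone, with a median of 0.17 (camera adjusted p = 3.4e-08, adjusted p = 0.170 with an estimated correlation). The 2 were Socs3 (1.24), a feedback inhibitor of cytokine signalling, and Srgn (0.78), a granule proteoglycan that leukocytes also make. The list median was 0.09 without AxL 1, where the list still passed (adjusted p = 1.6e-06). Gfap, the intermediate filament of astrocytes, had a log2 change of -0.02 (adjusted p = 0.918), and its sign was positive after quantile (0.11) or cyclic loess (0.11) normalization.

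**Figure D2:**
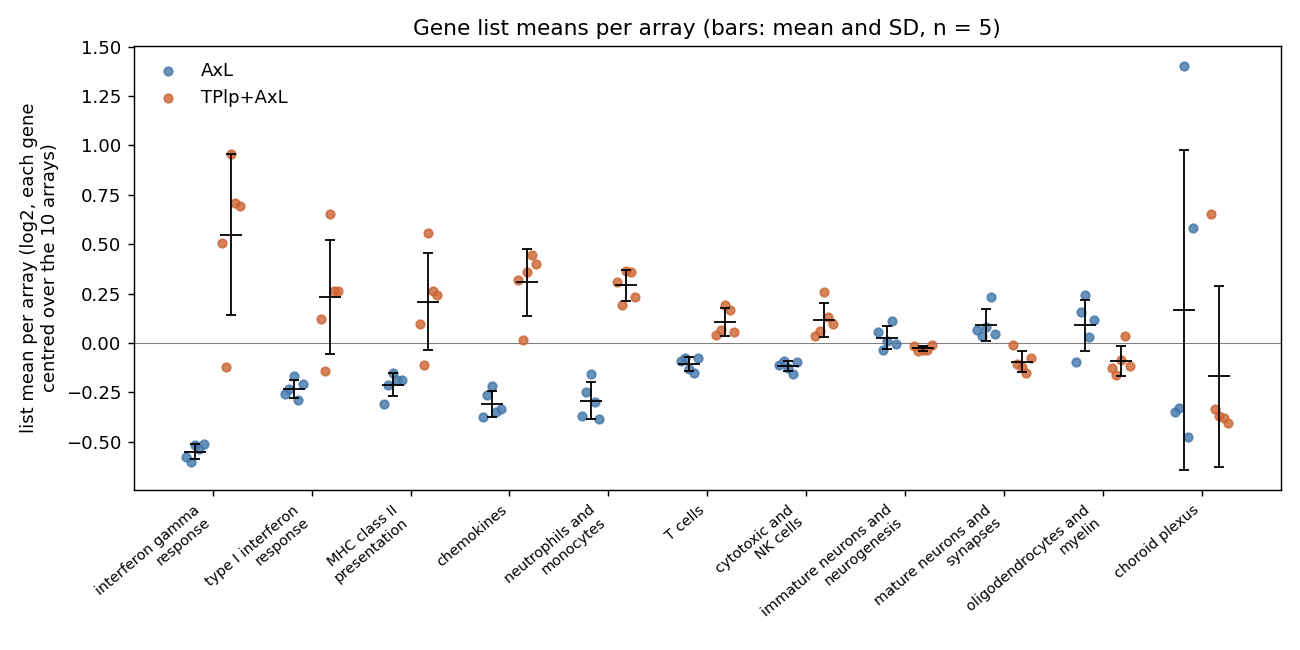
Mean of each gene list per array, with each gene centred over the 10 arrays (log2, vertical axis), for 11 lists; points are arrays, bars the mean and SD of 5 arrays per group. In the lists from the interferon gamma response to cytotoxic and NK cells every TPlp+AxL array lies above every AxL array, and in the choroid plexus list AxL 3 (1.40), AxL 5 (0.58) and TPlp+AxL 1 (0.65) stand above the rest.

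By the brightest probe set of each gene, the 12 largest declines were those of Ccl3, the membrane protein Itm2a (-0.52), the tubulin Tubb4a (-0.50), Nnat (-0.49), a membrane proteolipid of neurons, the iron exporter Slc40a1 (-0.48), Adgrf5 (-0.48), Ptprb (-0.44) and Sox17 (-0.36), which endothelial cells express, cortexin (Ctxn1, -0.43), Ptms (-0.38), the synaptic vesicle protein Syn1 (-0.37) and the stathmin Stmn4 (-0.36). Adjusted p ran from 0.00115 for Slc40a1 to 0.0462 for Ccl3 and Sox17, and all 5 TPlp+AxL arrays lay below all 5 AxL arrays in each gene. Other probe sets of Slc40a1 (-0.03), Sox17 (-0.02), Adgrf5 (-0.31), Itm2a (-0.34), Ptms (-0.17) and Ptprb (-0.31 and 0.02) did not pass. Dimmer probe sets of Cfl1 (-0.58, adjusted p = 0.00392), the actin-severing cofilin, and Pltp (-0.56, adjusted p = 0.00257), a phospholipid transfer protein, passed with larger declines than most of these, while the brightest of Cfl1 (-0.14, adjusted p = 0.317) and Pltp (-0.46, adjusted p = 0.239) did not pass.

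The list of mature neurons and synapses had a median log2 change of -0.17, with 21 of 22 members negative, 0 past the threshold over all genes in limma and 7 lower when adjusted over the list alone (camera adjusted p = 2.7e-06, adjusted p = 0.130 with an estimated correlation). Its members with the smallest p were the synaptic vesicle proteins Syp (-0.36, adjusted p = 0.0663) and Syt1 (-0.24, adjusted p = 0.117), and other probe sets of Syp (0.10) and Syt1 (0.11, 0.09 and 0.14) were positive. Syp passed without AxL 4 (adjusted p = 0.0188), and its limma adjusted p was 0.179 without TPlp+AxL 4. The myelin list had a median of -0.17, with all 17 members negative, 0 past the threshold in limma and 3 lower when adjusted over the list alone (camera adjusted p = 0.000135, adjusted p = 0.292 with an estimated correlation). Mobp, a myelin protein, had -0.36 (adjusted p = 0.0752) and Fa2h, an enzyme of myelin lipid synthesis, -0.26 (adjusted p = 0.122). Mobp passed without AxL 1 (adjusted p = 0.0479), and its limma adjusted p was 0.187 without TPlp+AxL 3. Genes of hippocampal subfields had a median of -0.11 (camera adjusted p = 0.0247, adjusted p = 0.286 with an estimated correlation), with 1 of 18 lower, Nnat, both over all genes and when adjusted over the list alone, and its median was -0.18 without AxL 2 (adjusted p = 0.0112).

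Signal level moved with these groups. The median change of all probe sets was 0.03 at mean levels of 7 to 8 and -0.14 at mean levels over 12, where 30 of the 85 lower and 0 of the 291 higher probe sets lay. After quantile normalization was repeated, which left medians of -0.0049 and 0.0024 at those levels, the mature neuron list had a median of -0.05 (adjusted p = 0.0561), the myelin list -0.11 (adjusted p = 0.0133) and the subfield list -0.04 (adjusted p = 0.301). After cyclic loess normalization, which left medians of -0.0011 and -0.0083, the 3 lists had -0.06 (adjusted p = 0.0165), -0.10 (adjusted p = 0.00431) and -0.03 (adjusted p = 0.225), so the mature neuron call was lost with the first normalization and kept with the second. The subfield call was also lost without AxL 1 (adjusted p = 0.101) or TPlp+AxL 5 (adjusted p = 0.0655).

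**Figure D3:**
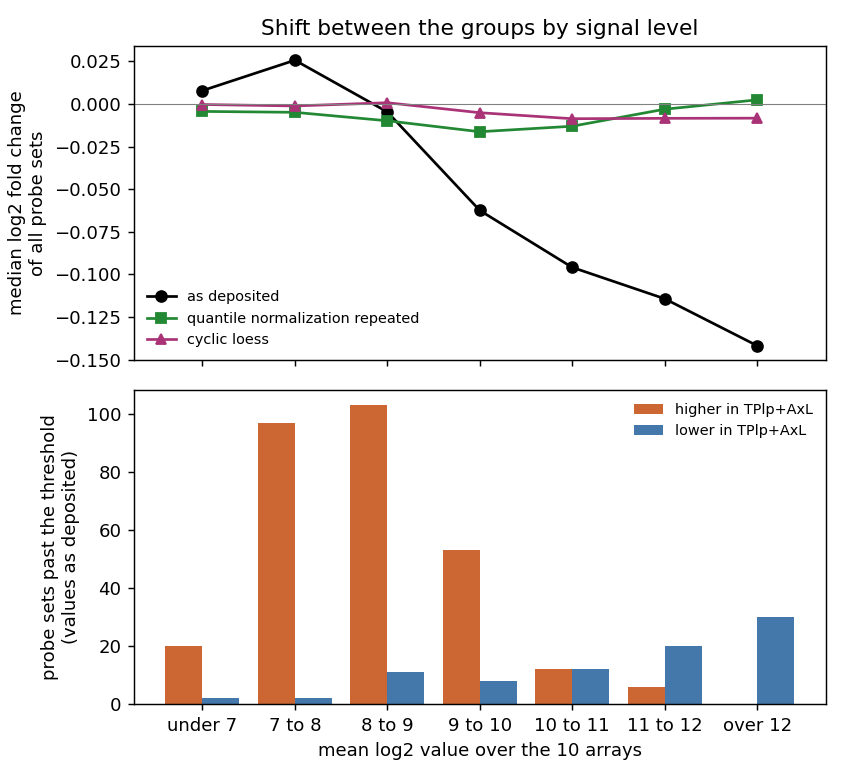
Upper panel, median log2 fold change (TPlp+AxL minus AxL) of all probe sets against their mean log2 value, as deposited and after 2 further normalizations; lower panel, number of probe sets past the threshold in each range of mean value, as deposited. As deposited the median runs from 0.03 at 7 to 8 to -0.14 over 12, and 30 of the 85 lower probe sets lie over 12.

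The series title names Dpysl3, a phosphoprotein of growing axons that marks immature neurons, and asks whether its mRNA after the lesion depends on myelin-specific T cells. Dpysl3 did not pass the threshold in any of its 3 probe sets. The brightest had a log2 value of 10.27 ± 0.23 (SD, n = 5) in AxL and 10.15 ± 0.16 (SD, n = 5) in TPlp+AxL, a change of -0.12 (SE 0.11, 95% interval -0.35 to 0.12, adjusted p = 0.627, exact permutation p = 0.397), with overlapping groups. The probe set of middle brightness was higher in all 5 TPlp+AxL arrays than in any AxL array, 8.98 ± 0.01 (SD, n = 5) against 8.84 ± 0.07 (SD, n = 5). Its change was 0.14 (95% interval 0.06 to 0.22, limma adjusted p = 0.117), and its exact permutation p of 0.00794, the smallest possible, was 0.0238 after adjustment over the 3 probe sets. The dimmest probe set had a change of 0.07 (95% interval -0.06 to 0.20, adjusted p = 0.599, exact permutation p = 0.278). That change was 0.11 without AxL 1, 0.03 without AxL 2 and 0.04 without TPlp+AxL 4. The change of the brightest probe set was -0.19 without AxL 2 and -0.03 without AxL 4, and it did not pass in either case.

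**Figure D4:**
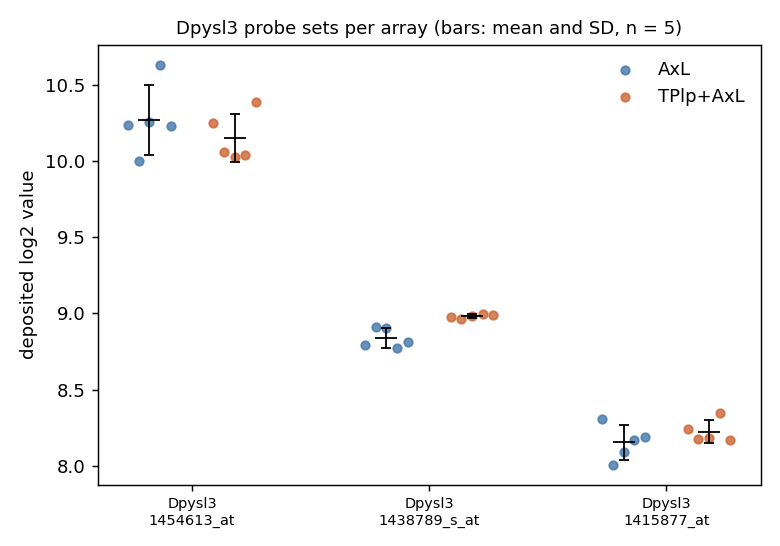
Deposited log2 value (vertical axis) of the 3 Dpysl3 probe sets in the 5 AxL and 5 TPlp+AxL arrays; points are arrays and bars the mean and SD. The groups overlap in the brightest and the dimmest probe set and are apart in the middle one, with means of 8.84 and 8.98.

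Other genes of newly formed neurons were also compared. In the list of immature neurons and neurogenesis 0 of 24 members passed in limma, over all genes or when adjusted over the list alone, and the median was -0.05 (camera adjusted p = 0.780, adjusted p = 0.815 with an estimated correlation), whereas fry gave an adjusted p of 0.0439 toward lower values. That median was -0.03 without AxL 4 and -0.08 without AxL 5 or without TPlp+AxL 5. Dcx, a microtubule-associated protein of migrating neuroblasts, had a log2 change of 0.04 (95% interval -0.09 to 0.16, adjusted p = 0.770), and its other probe sets had -0.07, -0.04 and 0.11. Islr2 (-0.31, adjusted p = 0.247) and the transcription factor Neurod2 (-0.22, adjusted p = 0.211) had the smallest p of the list. The list of neural stem and progenitor cells had a median of -0.08 with 17 of 19 members negative and 0 past the threshold in limma, also when adjusted over the list alone (camera adjusted p = 0.0435, adjusted p = 0.228 with an estimated correlation). Prom1 (-0.31, adjusted p = 0.152), a surface protein of progenitors, and Id4 (-0.23, adjusted p = 0.20), an inhibitor of differentiation, had its smallest p.

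The call of the stem cell list was lost after quantile normalization (adjusted p = 0.0859) and without AxL 2 (0.0523), AxL 3 (0.0812), AxL 4 (0.108), TPlp+AxL 1 (0.0507) or TPlp+AxL 5 (0.0939). Proliferation genes, in the cell cycle list, had a median of 0.02 with 23 of 37 members positive and 0 past the threshold in limma, also when adjusted over the list alone (camera adjusted p = 0.00687, adjusted p = 0.593 with an estimated correlation). Without TPlp+AxL 3 that call was lost (adjusted p = 0.267) and the median was -0.0075. The median was 0.0078, 0.035, 0.032, 0.075 and 0.011 without AxL 1 to 5, and 0.0036, 0.046 and 0.034 without TPlp+AxL 1, 2 and 5, with the call kept. After subtraction of each array's median the list median was -0.0083 while camera stayed positive. The replication factor Mcm3 had 0.14 (adjusted p = 0.246), with -0.07 and -0.02 in other probe sets, and thymidine kinase Tk1 had -0.16 (adjusted p = 0.20).

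Of the 32 lists, 18 passed in camera, 14 higher and 4 lower, and 4 of them passed with an estimated correlation: interferon gamma response, neutrophils and monocytes, chemokines and cytokines. Other divisions of the 10 arrays into 5 and 5 gave a median of 10 lists past the threshold in camera. Every TPlp+AxL array's list mean lay above every AxL array's in 10 of the 14 higher lists, and below in 1 of the 4 lower lists, mature neurons and synapses. Of the 54 named genes past the threshold, 20 no longer passed with at least 1 of the arrays left out: Gbp6, Psmb9, Tap1, Tapbpl, Zbp1, Dtx3l, Cd3d, Klrd1, Nkg7, S100a8, S100a9, Lyz2, Ccl3, Nnat, Tubb4a, Adgrf5, Ptprb, Sox17, Syn1 and Stmn4. Their highest adjusted p ran from 0.0570 (Tubb4a) to 0.132 (Ccl3), none changed sign, and calls ended in 4 (TPlp+AxL 2) to 18 genes (TPlp+AxL 4) depending on the array.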

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

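The tests of signal level as the whole cause of the lower calls and of endothelial genes, and the block for a division of the arrays, were chosen only after the result was seen. In 20 of 294 groups of 5 arrays (6.80%, where chance gives about 1 in 20), 1 array lay far from the other 4 relative to the spread of all 5.

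TPlp+AxL 2 had the lowest list mean of its group for the interferon gamma response (-0.12, others 0.50 to 0.96) and for MHC class I presentation (-0.18, others 0.20 to 0.91), and the lowest value of genes such as Gbp6 (8.91, others 10.38 to 11.31) and Cxcl10 (9.92, others 11.01 to 11.48). By the measure of distance from the other 4 it stood apart in 4 genes. Its log2 value was 10.15 for Gbp2 (others 11.36 to 11.54), 7.84 for Parp14 (others 8.26 to 8.40), 10.12 for Socs3 (others 10.63 to 10.82) and 10.38 for Tgfbr1 (others 10.60 to 10.61). The first 3 lie nearer to the AxL arrays than the others do and Tgfbr1, with an AxL mean of 10.78, further from them, while its Chil3 value of 10.63 was level with the highest of the group. Its mean for reactive microglia and macrophages was -0.048 (others 0.18 to 0.24). AxL 4 had 12.24 for Syp (others 11.82 to 11.91), 8.45 for Clec7a (others 8.20 to 8.27), 10.19 for Cry2 (others 9.66 to 9.75) and a mean of 0.23 for mature neurons and synapses (others 0.04 to 0.08). Its highest correlation with any other array was 0.993 (others 0.996 to 0.996). TPlp+AxL 1 had 8.72 for Kl (others 7.80 to 7.99) and 8.45 for Ace (others 8.16 to 8.24), both choroid plexus genes, and list means of 0.65 for choroid plexus (others -0.40 to -0.33), 0.091 for heat shock (others -0.10 to -0.05) and 0.014 for axonal growth and neurotrophic factors (others -0.06 to -0.04). It also had 7.04 for Cd79b (others 6.94 to 6.96). Single values stood apart for Ccl3 in TPlp+AxL 3 (7.77, others 8.43 to 8.63), Cd3e in TPlp+AxL 4 (8.89, others 8.96 to 8.98), Syn1 in TPlp+AxL 5 (11.35, others 11.12 to 11.13) and Parp14 in AxL 2 (7.55, others 7.65 to 7.69).

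The 85 lower probe sets fell, and the list of mature neurons passed toward lower values with 0 of 22 members past the threshold in limma (camera adjusted p = 2.7e-06, adjusted p = 0.130 with an estimated correlation, adjusted p = 0.0561 after quantile normalization and 0.0165 after cyclic loess), while the median change of all probe sets at high levels was negative too, although single bright genes such as Lyz2 (0.90) and Srgn (0.78) rose. After repeated quantile normalization 25 of the 85 still passed and all 85 were still negative. Their median went from -0.28 (SD 0.10) to -0.19 (SD 0.13), so the changes became smaller and more spread. The 85 were picked for being lower in these same arrays, so this cannot decide whether signal level was their whole cause. Over all probe sets 66 passed as lower after that normalization, so some lower calls were made with the trend by level largely removed. Signal level may account for at least part of the decline. A set of 48 genes picked by the symbols of ribosomal proteins had a median of -0.12 (95% bootstrap interval -0.14 to -0.09) against -0.15 for all probe sets of the same level. The set also holds related genes such as Rps19bp1. Its mean levels ran from 6.65 (Rpl3l) to 14.14 (Rps29), so not all of its members are abundant. The bootstrap intervals in this section resample genes, not mice, so they leave out the spread between mice. Added leukocytes could also lower the share of neuronal RNA, which predicts equal declines in mature and immature neurons; after quantile normalization the difference of their medians was -0.050 (95% bootstrap interval -0.13 to 0.02), with -0.05 (-0.10 to -0.02) for mature and -0.0037 (-0.06 to 0.05) for immature neurons. The mature neuron list lies at high levels (median 11.86), where quantile normalization takes out a fall shared by bright probe sets. A decline from dilution could be taken out with it, so that test cannot tell dilution from a shift with signal level. It leaves the dilution open under a rule made stricter after the values were seen. As first written, the rule asked only that the lists be lower and not differ, which would count for the dilution. The later rule also asks that each interval lie below 0. An effect of the T cells on neurons was not tested.

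The fixed list of endothelium and leukocyte adhesion did not pass (camera adjusted p = 0.440), and its adhesion genes Selp and Icam1 rose. A subset of 11 genes that define endothelial cells, picked from that list after its values were seen, had a median of -0.17 with all 11 negative, from Cldn5 (-0.51) to Kdr (-0.04), and 0 past the threshold over all genes in limma, so whether such genes are lower as a group is open. The 11 genes lay at mean levels from 6.76 (Tie1) to 9.60 (Slco1a4), where the median change of all probe sets was between 0.03 and -0.06. So small a shift argues against signal level as the cause of their median of -0.17. Quantile normalization could move these genes little, and left a median of -0.16 (95% bootstrap interval -0.27 to -0.10) with all 11 negative. A lower share of vessel RNA beside added leukocytes and a response of the vessels to the T cells may each account for it, and neither was tested.

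A division of the arrays that crosses the groups, AxL 1, AxL 4, AxL 5, TPlp+AxL 1 and TPlp+AxL 5 against the rest, had 1571 probe sets past the threshold, several times the 376 of the real groups, which points to a structure of the arrays. None of these (0 in limma) was among the 376, and with the division as a block 463 probe sets passed between the groups, 324 higher and 139 lower, with 284 of the 291 and 79 of the 85 shared. A candidate explanation is a measurement difference that acts on single probe sets: in 672 genes with a brighter second probe set, such as Hpca (1.51 against 0.31), the brighter one moved by 36.6% (95% bootstrap interval 33.6% to 40%) of the called one. The same measure was 58.1% (34.2% to 79.9%, 41 genes) for the higher calls between the groups, an overlapping interval; of the array measures, the 3' minus 5' signal of Gapdh did not differ between the sides (exact permutation p = 0.50) and the upper quartile of signal did (9.16 against 9.08, exact permutation p = 0.0238, unadjusted). In both comparisons the called probe set was picked for its p in these same arrays and the brighter one was not. A smaller shift of the brighter one is therefore expected even where the transcript itself differs. These percentages cannot decide for or against a measurement difference. No sample label follows the division that crosses the groups, so no biological explanation was tested.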

How the results depend on the processing

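Cyclic loess normalization, the block for a division of the arrays and the 2 settings that leave out several arrays were chosen only after the data were seen. No named gene past the threshold changed sign in any setting (0 of 54 in limma), with 1012 comparisons on the same side of the threshold and 213 no longer past it; 4 of the 18 lists past the threshold (interferon gamma response, neutrophils and monocytes, chemokines, cytokines) passed in every setting. Only Chil3 (1 of the 54) passed in every setting. The change of the brightest Dpysl3 probe set stayed negative and did not pass in any setting, nor did its other probe sets. The cause of the moves below was not tested. The higher count was 191 without the dim probe sets and the lower count 210 with array medians subtracted. Array weights gave 753 (465 higher, 288 lower). Same-numbered arrays are different mice and were not treated as pairs in the main test. Correlations of their deviations from the group means were -0.22 to 0.36, which cannot exclude shared handling. The replicate block gave 241, with 38 lower. The lower count was 44 with the choroid plexus covariate, 43 with cyclic loess, 54 with AxL 4 and TPlp+AxL 2 left out and 139 with the block for the division. With AxL 3, AxL 5 and TPlp+AxL 1 left out, which leaves 3 against 4 arrays, 1 probe set passed, 1 higher (Chil3) and 0 lower in limma, with 4743 at an unadjusted p under 0.05, while 16 lists passed. At an adjusted p under 0.10 the count was 757, and with an estimated correlation 4 lists passed, against 15 by fry. With 1 array left out the total ran from 185 (without TPlp+AxL 4) to 460 (without AxL 2), the higher from 159 (without TPlp+AxL 4) to 387 (without TPlp+AxL 2) and the lower from 26 (without TPlp+AxL 4) to 187 (without AxL 2). By array the total, higher and lower counts were 220, 188 and 32 without AxL 5, 240, 212 and 28 without TPlp+AxL 3, and 243, 196 and 47 without TPlp+AxL 5; the lower count was 36 without AxL 3 and 41 without TPlp+AxL 2. Calls of named genes ended in 16, 6, 11, 9 and 15 cases without AxL 1 to 5 and in 9, 4, 9, 18 and 13 without TPlp+AxL 1 to 5. Some values near 0 changed sign. Gfap was 0.11 after quantile and 0.11 after loess normalization, 0.011 with array weights, 0.015 with the choroid plexus covariate, 0.035 with AxL 4 and TPlp+AxL 2 left out, and -0.062 to 0.017 with 1 array left out (positive without AxL 3, AxL 4 or TPlp+AxL 5). The blood list was -0.011 with medians subtracted, -0.010 after quantile and -0.0021 after loess normalization, -0.016 with array weights, -0.049 with AxL 4 and TPlp+AxL 2 left out, -0.0097 with the block for the division, -0.0019 with probe sets averaged, and -0.032 to 0.046 with 1 array left out (negative without AxL 4 or TPlp+AxL 2). The heat shock list was 0.023 after quantile and 0.028 after loess normalization. The neocortex and subiculum list was 0.0017 after quantile and 0.014 after loess normalization, 0.021 with array weights, 0.0069 with the 3 arrays out and 0.0095 with AxL 4 and TPlp+AxL 2 out. Without the probe sets for shared sequence Bpgm was 1.5e-05 and Mcm3 -0.066. The choroid plexus list was 0.0088 with the 3 arrays out, Dcx was -0.011 and the immediate early list 0.022 with AxL 4 and TPlp+AxL 2 out, and the cell cycle list ran from -0.0075 (without TPlp+AxL 3) to 0.075 with 1 array left out.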

Other observations

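Of the tests below, the one of haemoglobin was chosen only after the result was seen. Among genes of vessels and leukocyte adhesion, 2 adhesion molecules rose while the other members of their list did not. In the list of endothelium and leukocyte adhesion 2 of 20 members were higher over all genes, and 2 were higher and 6 lower when adjusted over the list alone, with a median of -0.08 (camera adjusted p = 0.440). The 2 were P-selectin (Selp, 0.84, adjusted p = 0.00115), which lets leukocytes roll on the vessel wall, and Icam1 (0.74, adjusted p = 0.00407), which holds them there, and in both genes all 5 TPlp+AxL arrays lay above all 5 AxL arrays. A further Selp probe set had 0.56 and did not pass. In homeostatic microglia 0 of 18 members passed in limma and 4 were lower when adjusted over the list alone, with a median of -0.11 (camera adjusted p = 0.114). Trem2 (-0.33, adjusted p = 0.133), a lipid receptor of microglia, and Tgfbr1 (-0.22, adjusted p = 0.115), a receptor for transforming growth factor beta, had its smallest p, and other Tgfbr1 probe sets had 0.03 and 0.02. Trem2 passed without AxL 4 (adjusted p = 0.0141), and its limma adjusted p was 0.297 without TPlp+AxL 3. In oligodendrocyte precursors 0 of 11 passed in limma and 3 were lower when adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.0552), and all 5 TPlp+AxL list means lay below the 5 AxL means. It passed without AxL 1 (adjusted p = 0.0289), AxL 5 (0.0363) or TPlp+AxL 4 (0.0318), and homeostatic microglia passed without TPlp+AxL 1 (0.0466). The median of homeostatic microglia was -0.06 without TPlp+AxL 2 (camera adjusted p = 0.396). That of the precursors was -0.09 without AxL 3 (camera adjusted p = 0.0944). Bcas1 (-0.28, adjusted p = 0.0845), a gene of newly forming oligodendrocytes, and the transcription factor Olig1 (-0.28, adjusted p = 0.191) had its smallest p, and another Bcas1 probe set had 0.0019. Bcas1 passed without AxL 1 (adjusted p = 0.0423), and its limma adjusted p was 0.213 without TPlp+AxL 3.

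Lists for activity, growth and daily rhythm had 0 members past the threshold in limma. Axonal growth and neurotrophic factors had a median of -0.07 (camera adjusted p = 0.436), with Rgma (-0.18, adjusted p = 0.122), a repulsive guidance molecule, and Basp1 (-0.17, adjusted p = 0.157), a growth cone protein. Immediate early genes had -0.13 (camera adjusted p = 0.342), with the scaffold gene Homer1 (-0.20, adjusted p = 0.262) and Nr4a3 (-0.15, adjusted p = 0.313), whose other probe sets included 0.06 for Homer1 and 0.08 and 0.09 for Nr4a3. That list median ran from -0.18 (without AxL 2) to -0.0024 (without AxL 4) with 1 array left out, and the list mean was 0.59 in AxL 4 against -0.22 to 0.08 in the other AxL arrays. The circadian clock list had -0.09 (camera adjusted p = 0.0999), with Clock (-0.10, adjusted p = 0.278) and Cry2 (-0.22, adjusted p = 0.310), and other Clock probe sets had 0.02 and 0.12. The glucocorticoid response had -0.09 (camera adjusted p = 0.887), with Map3k6 (0.13, adjusted p = 0.285) and Per1 (-0.15, adjusted p = 0.424). Its median ran from -0.17 (without TPlp+AxL 5) to -0.03 (without AxL 3) with 1 array left out. Without AxL 3 the circadian median was -0.05 and the axonal growth median -0.04. Heat shock genes had -0.06 (camera adjusted p = 0.257), with the chaperones Hspd1 (-0.19, adjusted p = 0.277) and Cryab (-0.24, adjusted p = 0.331), and that median was 0.02 after quantile normalization. When adjusted over the list alone, 0 members of these 5 lists were higher or lower.

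Genes of adjoining tissues were listed to follow dissection. Meninges and fibroblasts had a median of -0.11 (camera adjusted p = 0.233), 0 of 20 members past the threshold in limma, and 1 higher and 2 lower when adjusted over the list alone. Its smallest p were those of the collagen Col6a2 (0.14, adjusted p = 0.132), with -0.02 in another probe set, and Islr (-0.29, adjusted p = 0.147). For the thalamus and habenula list and the list of neocortex and subiculum the median (-0.04 and -0.02) and mean (-0.04 and -0.04) were negative while camera's direction was positive (adjusted p = 0.858 and 0.959), and 0 members passed, also when adjusted over the list alone. Their members with the smallest p were Rgs16 (0.18, adjusted p = 0.191) and Synpo2 (0.11, adjusted p = 0.353) for the first and Crym (-0.17, adjusted p = 0.150) and Rspo1 (0.13, adjusted p = 0.348) for the second, and other Synpo2 probe sets had -0.14 and -0.07. The choroid plexus list had a median of -0.29 with 17 of 18 members negative and 0 past the threshold, also when adjusted over the list alone (camera adjusted p = 0.324). Its median was -0.02 without AxL 3 (adjusted p = 0.572) and -0.18 without AxL 5 (0.771), and it was -0.45 without AxL 4 (0.0396) and -0.48 without TPlp+AxL 1 (0.0411), where the list passed. The receptor-like Kl (-0.43, adjusted p = 0.572) had 0.02 in a second probe set, and the peptidase gene Ace had -0.20 (adjusted p = 0.484). Transthyretin (Ttr), the most abundant choroid plexus transcript, had log2 values of 14.71 in AxL 3, 14.73 in AxL 5 and 14.68 in TPlp+AxL 1, and 12.84 to 13.17 in the others. The pituitary hormone gene Prl, chosen after its values were seen, had 11.34 in AxL 3, 10.16 in AxL 5 and 9.62 in TPlp+AxL 4, against 7.24 to 8.62 in the others. With the choroid plexus list mean as a covariate, 244 probe sets were higher, against 291 without it, and 44 were lower, against 85 without it.

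Red cell genes were measured as a sign of blood left in the tissue. The blood list had a median of 0.02 with 0 of 6 members past the threshold, also when adjusted over the list alone (camera adjusted p = 0.395), and its median was -0.01 after quantile normalization. Its members with the smallest p were the anion exchanger Slc4a1 (0.07, adjusted p = 0.415), with -0.08 and -0.03 in other probe sets, and Bpgm (-0.09, adjusted p = 0.616), with 1.5e-05 in a second probe set. Over 15 haemoglobin probe sets the mean difference was 0.062 on the log2 scale (95% interval -0.40 to 0.53), and the brightest of them had a mean level of 11.87, so this measure leaves a difference in blood content open.

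Other divisions of the 10 arrays into 5 and 5 were fitted in the same way, 100 of them with the real one. In 2 of the 100, the real one included, at least as many probe sets passed as between the groups. The same held for the higher and for the lower probe sets. Such counts past the threshold were rare among the divisions. They do not exclude chance, since a division that crosses the groups gave more than the real groups. By an unadjusted p under 0.05 in limma the real groups had 6453 probe sets, and several other divisions had more, up to 10730. Counts by that looser measure were thus less rare. The real values past the threshold were 376, 291 and 85. The other division of the 2 had 1571 probe sets past the threshold, 1533 in one direction and 38 in the other, and since its sides have no order, its larger direction (1533) was set against both the higher and the lower count. For the number of gene lists chance cannot be excluded, since 11 of the 100 had as many as the real 18, and the others had a median of 10 and a highest count of 22.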
